A study of Homo sapiens with 12 samples.

How the data were processed

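Chromatin accessibility was measured by DNase-seq in 2 established human breast cancer cell lines, MCF-7 and ZR-75-1. In this assay, nuclei are treated lightly with the enzyme DNase I and short released fragments are sequenced, so that stretches of open chromatin collect more tags. Per the labels' protocols, cells were kept in medium with stripped serum and then left untreated or given 100 nM dexamethasone (dex) or 100 nM estradiol (E2) for 30 minutes. The 12 samples fall into 6 groups of 2. The labels name 1 region list for both samples of a group, so each list was treated as 1 observation and no value has a replicate error. Samples were grouped by the treatment and cell line given for each sample. One further label field names MCF-7 for the ZR-75-1 samples too, and the field that gives the cell line was followed.

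Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie2 were used and the genome build was hg19. The program that called the regions, its background model and the way in which the samples of a group were combined are not given in the sources used here. Per the file headers, each region has a position, a highest density, an average density, a score and a p-value. The deposited densities are a signal that is never negative, and the highest density is called the level below. The deposited score and the deposited p-value are the authors' own values for each region and served here only to describe or rank regions. The normalization of the deposited signal is not stated. Levels under 100 were whole multiples of 1 step in each list, within 0.05 of a step, for 100% of these values. The step was 0.101 in untreated, 0.100 in dex and 0.0931 in E2 lists of MCF-7, and 0.129, 0.110 and 0.130 in those of ZR-75-1. If a step stands for 1 tag, a smaller step means a deeper list, but the total number of tags is unknown. The Poisson intervals given for levels rest on that assumption and cover counting error alone. In both comparisons of the dex list of ZR-75-1, noise simulated in the same way gave more regions over 2-fold than were observed. It gave fewer under 0.5-fold, so the intervals may be too wide there, but this is not settled. Region numbers run beyond the number of regions in each list, to 89309 for the 82446 regions of the untreated MCF-7 list, so that some numbers are missing from the deposited lists. Starts count from 0, since 1 region starts at 0, and positions are given here from 1, so that a start could be off by 1 bp.

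Lists were compared with bedtools 2.31.1, and regions that shared at least 1 bp counted as shared. Shares have exact binomial 95% intervals, which cover counting error only. A region of a treated list that overlapped no untreated region is called gained, and a region of the untreated list that overlapped no treated region is called lost. These words describe the lists and not a test. Regions of the 6 lists that overlapped were merged for comparisons over more than 1 pair of lists. Overlaps of gained regions were tested with Fisher's exact test, two-sided. The planned table for dex-gained against E2-gained regions of 1 cell line has an empty cell by construction, since each of its regions is in a treated list, and its odds ratio says nothing. A background of all merged regions without an untreated region of that cell line was used in its place. Regions are not independent replicates, so p-values over regions describe these lists.

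For regions in all 6 lists, log2 levels were centred on the median of each list, which removes any single scale factor per list. They were fitted with limma 3.58.1 (R 4.3.3, empirical Bayes with a trend on the mean level) with terms for cell line and treatment, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The cell lines are the replicates of this model. It has 2 residual degrees of freedom, and its error comes from the disagreement between the cell lines, pooled over regions (142 prior degrees of freedom). It tests the mean change over the cell lines, and a region can be called though they disagree. It requires a region in every list and leaves out gained and lost regions. This model, the ligand-matched table and the correlations between cell lines were chosen after the data were seen. Counts under several scalings had been looked at before median centring was settled on, each with and without robust empirical Bayes. The closing section gives the counts of each. In simulated lists with residuals of the real size, the model for dex over 44817 regions recovered 67 of 100 regions changed 2-fold and 100 of 100 changed 4-fold, with 1 call among unchanged regions. The simulated noise was independent between regions and between lists, so that 1 call does not measure the false calls in real lists. The overlap functions returned the known classes of simulated intervals.

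Choices of comparison, overlap, alternatives and named regions were otherwise made before the data were examined. The rule named, for each comparison, the 10 gained and 5 lost regions of the highest level. Its parts on genes were not applied. The annotation at hand is of another build, and a genome of build hg19 was not used here, so regions are given by position, and motifs, promoters and lists of target genes were not analysed here. Chromosomes Y and M were left out of named regions. In the closing section, the tests on chromosomes 17 and 20 were written down after those chromosomes had been seen to stand out. For the level of ZR-75-1 regions there, a first calculation divided by regions found in all 6 lists instead of by the list median, which the prediction named. It gave 1.33 and would have excluded the explanation. The calculation as worded gave 1.74, which leaves it open, and that value is the one used. The test of depth for the shifts with E2 took the place of one on the number of regions per list, after the outcome of the latter had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.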

Results

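DNase-seq region lists were compared for MCF-7 and ZR-75-1 cells, both luminal breast cancer lines that respond to estrogen. Dexamethasone (dex) is a synthetic glucocorticoid that activates the glucocorticoid receptor, and estradiol (E2) activates the estrogen receptor. Each of the 6 groups had 2 samples and 1 deposited list, so no value below has a replicate error. The MCF-7 lists held 82446 regions in untreated, 88071 in dex-treated and 83205 in E2-treated cells. The ZR-75-1 lists held 101884, 111731 and 93745 regions in the same order. Median widths lay between 697 and 789 bp, and the lists covered 68.2 to 99.8 Mb. The median level, the highest density in a region, was 42 steps in untreated MCF-7 and 31 steps in untreated ZR-75-1. Merged over all lists there were 162940 regions, of which 44817 (27.5%) were in all 6.

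The untreated lists describe the open chromatin of each cell line before hormone. Of the MCF-7 regions, 33.0% (95% interval 32.7 to 33.3) overlapped no ZR-75-1 region, and 46.7% (46.4 to 47.0) of the ZR-75-1 regions overlapped no MCF-7 region. The ZR-75-1 list is the longer one. In lists of equal length, which bring the counts near each other by construction, 30289 MCF-7 and 31373 ZR-75-1 regions had no overlap. Regions in 1 cell line alone were weaker, with a median level of 2.94 against 5.37 for shared regions in MCF-7 and 2.84 against 6.08 in ZR-75-1. Merged regions in all 3 MCF-7 lists and no ZR-75-1 list numbered 10386, and 20080 were in all 3 ZR-75-1 lists and no MCF-7 list.

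Dex was compared with no treatment to see where accessible regions appeared or went within 30 minutes. In MCF-7, 19901 regions (22.6%, 22.3 to 22.9) of the dex list were gained and 14337 (17.4%, 17.1 to 17.7) of the untreated list were lost. In ZR-75-1, 22397 (20.1%, 19.8 to 20.3) were gained and 11213 (11.01%, 10.81 to 11.20) were lost. Gained regions were weak, with a median level of 2.71 in MCF-7 and 2.32 in ZR-75-1, against 5.82 and 5.19 for shared regions. Of the gained regions, 2042 in MCF-7 and 1134 in ZR-75-1 had a level over the median of their list. In lists of equal length, 16250 were gained and 16239 lost in MCF-7, and 9606 and 8549 in ZR-75-1. Equal lengths bring gains and losses close to each other by construction. The dex list of ZR-75-1 has a smaller step than the untreated one, 0.110 against 0.129. If the step reflects depth, depth and dex cannot be told apart for the excess of gains there.

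E2 was compared with no treatment in the same way. In MCF-7, 15908 regions (19.1%, 18.9 to 19.4) were gained and 14095 (17.1%, 16.8 to 17.4) lost. In ZR-75-1 the numbers were 12042 (12.9%, 12.6 to 13.1) gained and 20612 (20.23%, 19.98 to 20.48) lost, so that losses were the more numerous. Gained regions had a median level of 2.51 in MCF-7 and 1.95 in ZR-75-1. Those over the median of their list numbered 1185 and 639. In lists of equal length, 15362 were gained and 14298 lost in MCF-7, and 9663 and 10147 in ZR-75-1.

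**Figure D1:**
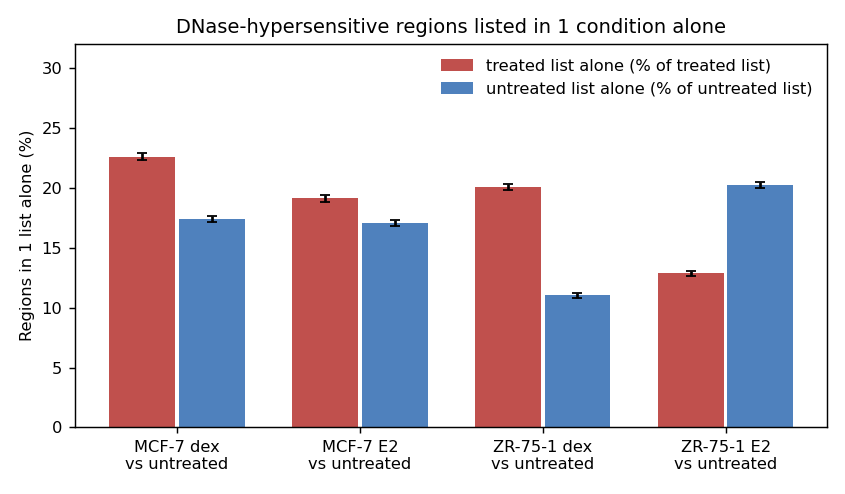
Bars give the percent of regions of the treated list that overlap no untreated region and the percent of the untreated list that overlap no treated region, with exact 95% binomial intervals for counting error only, for dex and E2 in both cell lines. E2 in ZR-75-1 is the comparison in which the untreated list has the higher share, 20.2% against 12.9%.

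The lists of the ligands were also set against each other. In MCF-7, 15958 dex regions (18.1%) overlapped no E2 region and 12168 E2 regions (14.6%) overlapped no dex region. In ZR-75-1 these numbers were 28332 (25.4%) and 8714 (9.3%). The dex list has the smaller step in this pair too, 0.110 against 0.130, so depth and ligand cannot be told apart here either. Of the merged regions without an untreated region, 8151 in MCF-7 were in both treated lists, 11081 in the dex list alone and 7106 in the E2 list alone. In ZR-75-1 the numbers were 4988, 17003 and 6624. Among merged regions without an untreated region of the cell line, independent lists would have shared 3513 regions in MCF-7 and 3981 in ZR-75-1. The odds ratios were 5.92 and 1.57, with Fisher's exact p of 3.26e-102 for ZR-75-1. Both gained lists leave out the same untreated list, so part of this excess may be built in. The background also counts regions that were listed in the other cell line alone. It held 83522 regions for MCF-7, of which 26338 were in a treated MCF-7 list, and 64140 for ZR-75-1, of which 28615 were. The excess thus depends on this background and says nothing about the ligands.

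The regions of the highest level among those gained lay on few segments in MCF-7. All 10 named dex-gained regions were on chromosomes 17 and 20, as were all 10 named E2-gained regions. The strongest by dex was at chromosome 17, 57991651 to 57992226, with a level of 60.4 (Poisson interval 55.7 to 65.5), and the strongest by E2 at chromosome 20, 49343636 to 49344730, with 63.9 (59.2 to 68.9). Both were in the list of the other ligand too, the first with 56.1 in E2 and the second with 42.7 in dex. Most other named gained regions of MCF-7 were also in both treated lists. What sets these regions apart is their absence from the untreated list, and they are not particular to 1 ligand. The 5 strongest lost regions of each comparison were on chromosome 20, and the first of them for dex, at 52308912 to 52309720, had a level of 57.1 (52.5 to 62.0). A dex region lies within 500 bp of that lost region, so it is not lost if regions so near count as shared. In the 7 windows of 1 Mb that held the named gained regions, the median level in the untreated MCF-7 list was 5.81 times the list median, against 1.74 times in untreated ZR-75-1. There were 107 gained and 172 lost regions by dex in these windows, and 90 and 124 by E2. Between the dex and E2 lists of MCF-7, all 15 named regions were again on these chromosomes.

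**Figure D2:**
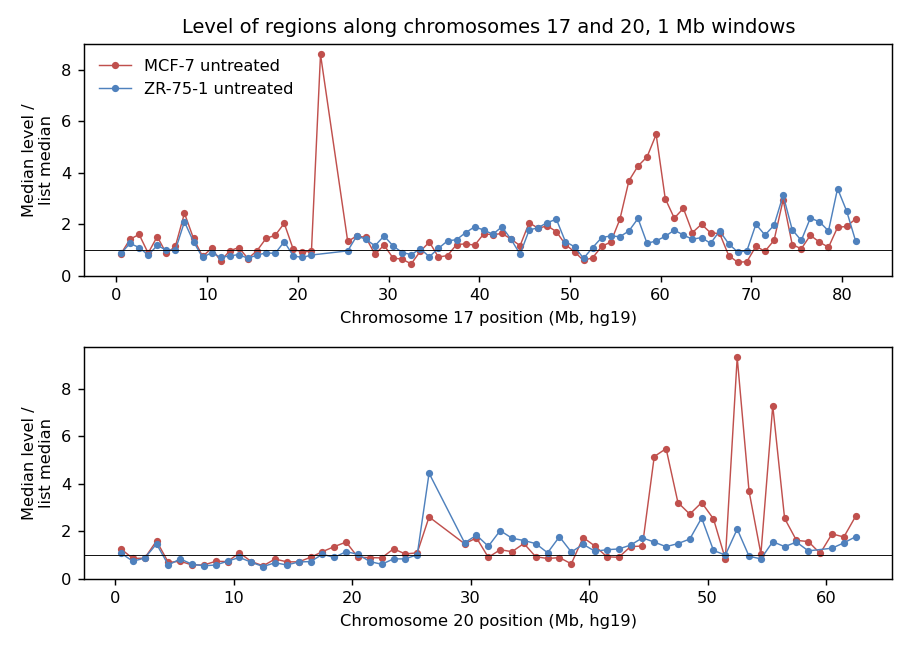
The median level of regions in windows of 1 Mb, divided by the median of the list, is drawn along chromosomes 17 and 20 (hg19 positions in Mb) for the untreated lists of MCF-7 and ZR-75-1, for windows with at least 5 regions. In MCF-7 the ratio reaches 9.33 on chromosome 20 from 52 Mb, where it is 2.10 in ZR-75-1.

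In ZR-75-1 the named regions were spread over more chromosomes. Of the 10 named dex-gained regions, 5 had a score under 10. Whether named regions with scores so low reflect open chromatin was not examined. The dex-gained region with the highest score lay at chromosome 11, 114049524 to 114050843, with a level of 25.4 (22.2 to 28.9) and a score of 114. An untreated region and an E2 region of ZR-75-1 lie within 500 bp of it, so it is not gained if regions so near count as shared. The level was higher at 2 other regions, 141.7 at chromosome 2, 92273433 to 92273683, and 26.3 at chromosome 2, 132987694 to 132987981, but their scores were 7.16 and 8.31, and both also have an untreated and an E2 region within 500 bp. Of the 10 named E2-gained regions, 5 had a score under 10, and the highest score, 41.3, was that of chromosome 6, 6703624 to 6704505, with a level of 12.5 (10.1 to 15.2). All 5 named regions lost with dex and 4 of the 5 lost with E2 had a score under 10. Between the dex and E2 lists of ZR-75-1, the same region of chromosome 2 at 92273433 was the strongest in dex alone. The strongest in E2 alone was at chromosome 11, 51574086 to 51574531, with a level of 41.8 (37.4 to 46.6). Each of these has a region of the other list within 500 bp, and the merged region that holds the second had ZR-75-1 levels of 277 in untreated, 259 in dex and 275 in E2 lists.

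Levels were compared at regions shared with the untreated list. The median log2 ratio was 0.15 for dex and 0.22 for E2 in MCF-7, and 0.16 for dex and -0.06 for E2 in ZR-75-1. The scale of the lists is not stated, so these shifts may not be read as changes of accessibility. In MCF-7, 1855 regions were over 2-fold with dex and 550 under 0.5-fold, but 607 and 946 once levels were divided by the median of regions in all lists of that cell line. With E2 the numbers were 1172 and 250, and 279 and 720 after this scaling. In ZR-75-1 they were 935 and 402 with dex, and 296 and 713 after scaling. With E2 in ZR-75-1 they were 551 and 974, and 683 and 868 after scaling. After each comparison was centred on its own median, 921 regions were over 2-fold and 742 under 0.5-fold for dex in MCF-7, against 204 and 220 in simulated counting noise. For E2 in MCF-7 there were 307 and 658 against 234 and 211. In ZR-75-1 there were 398 and 608 against 680 and 554 for dex, and 678 and 876 against 637 and 518 for E2. The simulated count for dex in ZR-75-1 exceeds the observed one over 2-fold but not under 0.5-fold. The simulation thus does not match the spread there and cannot show whether an excess exists.

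The cell lines share no control list, so regions gained in both were counted. Regions gained by dex in both numbered 2205, against 2596 for independent lists (odds ratio 0.81, Fisher's exact adjusted p = 3.96e-19 over 4 tests). For E2 in both there were 610 against 1087 (0.52, adjusted p = 2.13e-64). The crossed pairs gave odds ratios of 0.49 and 0.62. All 4 were under 1 over this background, and all 4 were over 1 for gained regions over the median level of their list. The background of 162940 merged regions includes regions with an untreated region of a cell line, which cannot be gained there. Expected counts, odds ratios and p-values thus depend on the background. Values under 1 do not show that shared gains are scarce. Among regions gained by 1 ligand alone in each cell line, 1007 were gained by dex in both, 96 by E2 in both, 67 by dex in MCF-7 and E2 in ZR-75-1, and 366 the other way round. The odds ratio for the same ligand was 3.94 (2.79 to 5.59, Fisher's exact p = 8.38e-16). In lists of equal length these counts moved to 405, 252, 190 and 173, with an odds ratio of 3.11 (2.38 to 4.06, Fisher's exact p = 3.29e-18). Over the median level of their list there were 16, 6, 2 and 6, with an odds ratio of 8.0 (0.978 to 94.7, Fisher's exact p = 0.0342). By the lower of their scores, chosen after the values were seen, the first region gained by dex alone in both was again chromosome 11, 114049524 to 114050843, with levels of 8.03 (6.37 to 10.0) in MCF-7 and 25.4 in ZR-75-1. Its gain in ZR-75-1 does not hold within 500 bp, as said above, and an E2 region of MCF-7 lies as near. The first for E2 was chromosome 1, 12660054 to 12661018, with 5.68 (4.35 to 7.30) and 6.62 (4.93 to 8.70), and it has untreated and dex regions within 500 bp in both cell lines. The next in rank were chromosome 2, 190818568 to 190819683, for dex and chromosome 14, 50459459 to 50460155, for E2. Neither has an untreated region or a region of the other ligand within 500 bp in either cell line.

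Level changes were compared between the cell lines over the 44817 regions in all lists. Across regions, which are not independent replicates, the changes by dex correlated with Pearson's r = 0.185 and Spearman's rho = 0.144, and those by E2 with 0.167 and 0.157. The crossed pairs gave r = 0.006 for dex in MCF-7 with E2 in ZR-75-1 and 0.025 for E2 with dex. The mean of the same-ligand values exceeded that of the crossed ones by 0.160 (0.153 to 0.167 over resampled windows of 1 Mb). Within a cell line, where dex and E2 share the untreated list, r was 0.403 in MCF-7 and 0.443 in ZR-75-1. Unchanged lists with counting noise gave 0.550 and 0.529, and covariances of 0.0389 and 0.0458 against the observed 0.0595 and 0.0400. These simulations rest on the same noise, which gave too many regions over 2-fold for dex in ZR-75-1.

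**Figure D3:**
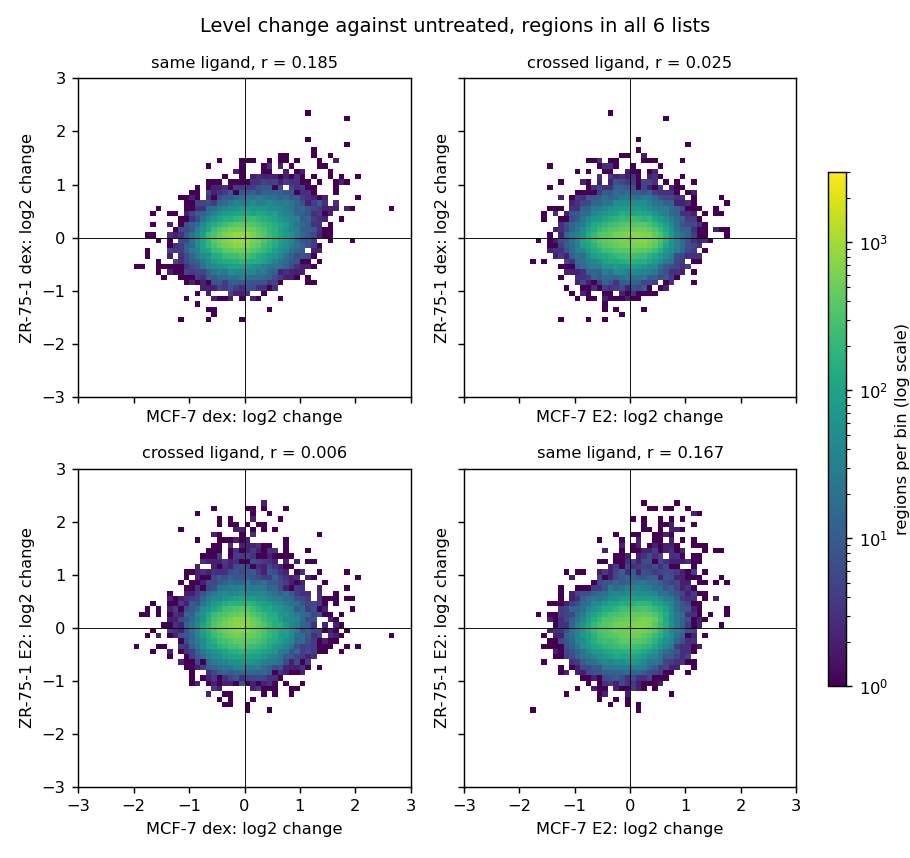
Each panel bins regions by their log2 level change against untreated in MCF-7 (horizontal) and ZR-75-1 (vertical), centred on the median, with the number of regions per bin on a log colour scale. The same-ligand panels have r = 0.185 and 0.167, and the crossed panels 0.025 and 0.006.

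A model over both cell lines tested the mean change over them. Dex raised 178 regions and lowered 37 of 44817, and E2 raised 214 and lowered 37, by limma with Benjamini-Hochberg adjustment. Without centring the splits were 301 and 4 for dex and 140 and 2 for E2. The numbers of raised and of lowered regions thus both depend on the centring, and so does which ligand raised more. A difference between whole lists is not excluded for these counts, least of all for the lowered regions. All raised regions were higher in both cell lines, and 27 of those raised by dex and 26 of those raised by E2 were over 2-fold in each. The calls favour the same sign, since the smallest mean rise called was a log2 of 0.684 for dex and 0.698 for E2. This agreement is thus no independent support. Of the 36 lowered by dex outside chromosomes Y and M, 35 were lower in both cell lines and 2 were under 0.5-fold in each. The exception, chromosome X, 115002891 to 115005629, changed by a log2 of -1.75 in MCF-7 and 0.09 in ZR-75-1. From untreated to dex its level went from 6.99 to 2.41 in MCF-7 and from 623 to 757 in ZR-75-1. Whether levels so high reflect open chromatin was not examined, for this or for other lowered regions of high level. All 37 lowered by E2 were lower in both cell lines, and 2 were under 0.5-fold in each. The region most firmly raised by dex was at chromosome 17, 55292096 to 55294067 (log2 change 2.07, SE 0.197, limma adjusted p = 6.80e-15). Its level went from 10.8 to 46.5 in MCF-7 and from 2.97 to 16.1 in ZR-75-1. Chromosome 5, 71043786 to 71046639, followed with a log2 change of 1.82 (SE 0.184, adjusted p = 1.75e-13), and E2 raised it too, by 1.08 (adjusted p = 4.06e-05). At chromosome 4, 78484845 to 78486271, the change was 1.56 with dex (adjusted p = 7.55e-09) and -0.02 with E2 (adjusted p = 0.979). The region most firmly raised by E2 was at chromosome 21, 43795256 to 43797557 (1.504, SE 0.187, adjusted p = 7.94e-09), where the level went from 27.6 to 95.5 in MCF-7 and from 3.36 to 8.83 in ZR-75-1. At chromosome 2, 11638166 to 11639599, E2 gave 1.43 (adjusted p = 7.94e-09) and dex 0.06 (adjusted p = 0.967). The most firmly lowered were chromosome 6, 112693280 to 112694045, with E2 (-1.69, adjusted p = 1.26e-05) and chromosome 2, 87623477 to 87624307, with dex (-1.12, adjusted p = 1.19e-04). These regions were named after their values were seen. Raised by both ligands were 12 regions, against 0.85 for independent lists, and lowered by both were 0 against 0.03. Chromosome 14, 93483334 to 93484341, was called in opposite directions. It was lowered by dex (-0.929, limma adjusted p = 0.0183) and raised by E2 (1.341, limma adjusted p = 2.41e-05). The dex and E2 changes share the untreated lists, which gave a covariance of 0.0253 in simulated unchanged lists against the observed 0.0258. The size of the simulated noise was taken from these same lists, treatment differences included, so this near match is largely built in. Independent noise with a shared control gave a correlation of 0.5, against the observed 0.37. These values cannot show whether the shared untreated lists account for the 12 regions raised by both.

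**Figure D4:**
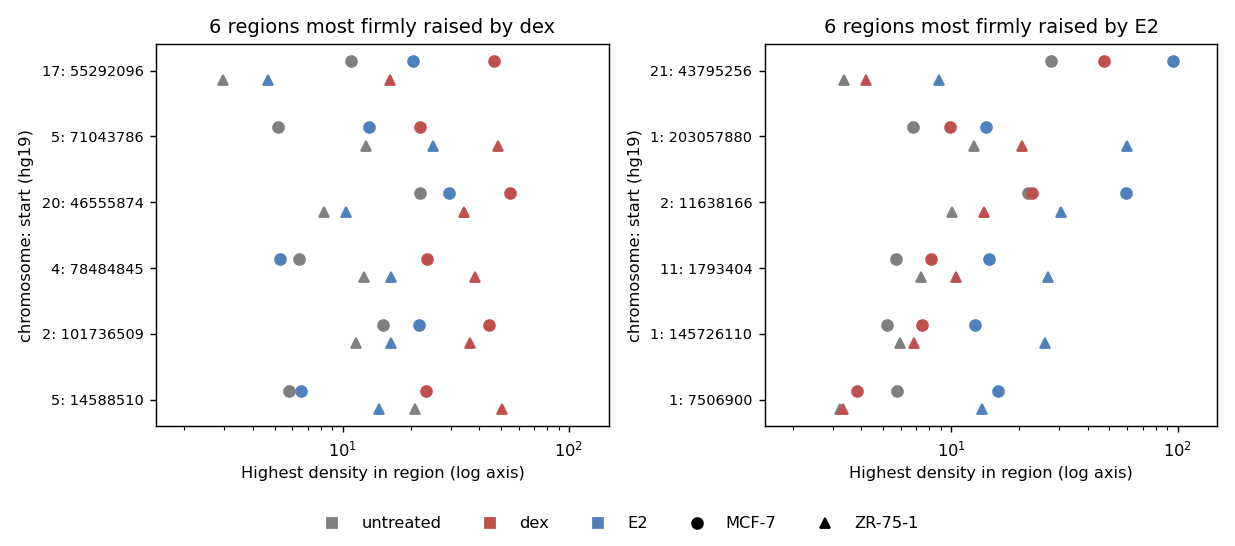
Levels (highest density, log axis) of the 6 regions with the lowest limma p for a rise by dex (left) and by E2 (right) are drawn for each of the 6 lists, with colour for treatment and shape for cell line. In every region drawn, the list of the named ligand has the highest level in both cell lines. The regions were chosen for a rise in these same levels, so this is no independent support.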

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

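The tests on chromosomes 17 and 20, on depth and on weak regions were chosen after the results they weigh had been seen. The other tests here were written down first.

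E2 went with opposite shifts in the cell lines. The median log2 level ratio at shared regions was 0.219 in MCF-7 and -0.064 in ZR-75-1, and regions gained for each region lost numbered 1.13 and 0.58. In lists of equal length these ratios were 1.07 and 0.95, and equal lengths bring them near 1 by construction. The difference between the cell lines was not tested, since each value comes from 1 pair of lists. The steps of the ZR-75-1 E2 and untreated lists differ by 0.43%, so, if the step reflects depth, a depth difference is argued against there. In MCF-7 the E2 step is lower (-8.13%), which goes with the ligand, so that depth and E2 cannot be told apart. A shift of whole libraries stays open. Within 1 SD of counting error, 86.8% of regions lay on the side of the shift in the cell line with the lower share, but this allowance puts most regions there even without a shift, so the value decides nothing. An effect of E2 itself stays open and untested.

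The strongest gained and lost MCF-7 regions lie on chromosomes 17 and 20. More copies of these segments in MCF-7 may account for it, as a hypothesis. The 10th percentile of the level in these windows was 3.85 times that of the untreated list, so that weak regions are raised there too, and in untreated ZR-75-1 it was 1.786 times that of the list. More opening by the ligand over these windows as a whole is argued against. Gained regions were fewer relative to lost ones in the windows than elsewhere (odds ratio 0.445 for dex, Fisher's exact p = 2.78e-11). This test counts all regions of the windows, weak ones included, so it does not decide whether the ligand opened the named ones. Regions that are strong in any cell line stay open in part, because ZR-75-1 regions there were 1.742 times the list median.

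Level changes matched between the cell lines by ligand. Weak regions near the limit of the lists are argued against as the whole cause, since among regions with a mean level over the median same-ligand correlations exceeded crossed ones by 0.217 (0.204 to 0.229), against 0.160 (0.153 to 0.167) over all regions. A dependence of the change on the level is argued against as the whole cause, since same-ligand correlations stayed 0.149 over crossed ones after quantile normalization and removal of the trend. The real labels of the ZR-75-1 lists gave 466 calls for dex and E2 together, and the highest of the other labellings gave 176. Of the 6 labellings, 1 gave as many as the real one, itself, and so few labellings cannot give a share under 0.05. That other labelling keeps the dex list and swaps E2 and untreated, and all its 176 calls were for dex, so it still sets the dex list of ZR-75-1 against another list of that cell line. For dex and E2 in turn, the remaining labellings gave 43 and 7, 0 and 42, 17 and 10, and 2 and 2 calls. A shared response to each ligand remains a hypothesis, found and tested on the same data.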

How the results depend on the processing

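The alternatives with average density, without centring, with the trend on level removed and without chromosomes 17, 20 and Y, and all those of the model over both cell lines, of the correlations and of regions gained by 1 ligand alone, were chosen after the data were seen. Of 201 values of comparisons under an alternative, 107 stayed within the spread or within 1.5 times the count, 89 moved further and 5 turned in direction. No paired analysis was possible because the labels name 1 list for both replicates of a group, and for the same reason no replicate was left out. Leaving out a cell line leaves the model no residual degrees of freedom. The motif, gene list and promoter alternatives were not run. The cause of the moves below was not tested except where the setting holds fewer regions. Requiring 50% overlap, counting regions within 500 bp as shared or merging them moved no count by over 1.5 times.

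Among regions over the median level of their list, 2042 were gained and 1325 lost with dex in MCF-7, 1185 and 1125 with E2 in MCF-7, 1134 and 315 with dex in ZR-75-1, and 639 and 1045 with E2 in ZR-75-1. In dex alone and in E2 alone there were 1307 and 1029 in MCF-7, and 1664 and 349 in ZR-75-1. Regions gained by both ligands fell to 512 and 221. The log2 odds ratio of regions gained in both cell lines turned positive in all pairs, at 2.07 for dex and 2.80 for E2, and 1.43 and 1.94 for the crossed pairs of MCF-7 dex and MCF-7 E2. With lists of equal length that for dex turned to 0.106. So the direction of that comparison depends on the setting. The setting over the median level took weak regions out of the gained sets but kept all 162940 merged regions as the background. It thus cannot show that weak regions set the direction. With lists of equal length, ZR-75-1 gained 9606 regions with dex and lost 10147 with E2, 10762 dex regions were not in the E2 list, and 31373 untreated regions were not in MCF-7. Regions gained by 1 ligand alone in each cell line then numbered 405 for dex in both, 252 for E2 in both, 190 for dex in MCF-7 and E2 in ZR-75-1, and 173 the other way round. Over the median level of their list they numbered 16, 6, 2 and 6. Within 500 bp they were 957, 89, 65 and 344. The odds ratio stayed over 1 throughout.

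Counts of shared regions over 2-fold and under 0.5-fold depended on scaling in most comparisons. Divided by the median of regions in all lists of the cell line, they were 607 and 946 for dex and 279 and 720 for E2 in MCF-7, and 296 and 713 for dex in ZR-75-1. Quantile normalization gave 851 over 2-fold for dex and 382 over and 509 under for E2 in MCF-7, and 441 over for dex in ZR-75-1. With 10 added to each level, the counts were 30 and 180, 11 and 48, 10 and 97, and 13 and 235 for dex and E2 in MCF-7 and then in ZR-75-1, with median log2 ratios of 0.053, 0.071, 0.057 and -0.022. Among regions with a mean level over the median they were 782 and 359, 601 and 114, 380 and 214, and 279 and 549 in that order, with medians of 0.142, 0.299, 0.179 and -0.055. Average density gave 639 over 2-fold for E2 in MCF-7 and 524 for dex in ZR-75-1, with medians of 0.126, 0.170, 0.144 and -0.043.

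Same-ligand correlations stayed positive throughout. For dex they were 0.169 with 10 added, 0.218 among regions over the median and 0.198 with average density, and for E2 0.219, 0.235 and 0.178. For MCF-7 dex with ZR-75-1 E2, values were 0.028 by quantile normalization, 0.027 with the trend removed, 0.020 with 10 added and -0.005 with average density. For MCF-7 E2 with ZR-75-1 dex it was 0.056 with 10 added. In the model, no centring gave 301 regions raised and 4 lowered by dex and 140 raised and 2 lowered by E2. With robust empirical Bayes these were 282, 4, 139 and 2. Quantile normalization gave 202, 31, 193 and 57, and 194, 31, 178 and 56 with robust empirical Bayes. Median centring with robust empirical Bayes gave 191, 41, 230 and 48. Regions lowered by E2 numbered 15 with 10 added, and 112 were raised by dex among regions over the median. Of the 90 named regions, 25 had a region of the other list within 500 bp. In ZR-75-1, regions lost with dex had a median height of 13 steps, regions gained with E2 of 15 and regions in E2 alone against dex of 12.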

Other observations

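The tests of distance below were written down before their results were seen, but the raised regions come from a model chosen after the data were seen.

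Regions raised by E2 lay close together. Of the 214, 15.9% had another raised region within 100 kb, against a median of 1.9% in 1000 random sets of tested regions of the same size on the same chromosomes, whose highest share was 9.3%. Of the 178 regions raised by dex, 6.7% had one, against a median of 2.2%, with a highest random share of 9.6%. The dex share stood above 99.4% of the random sets. Clusters of regions in general are thus argued against for E2 and, less firmly, for dex. The random sets were not matched on level. A candidate explanation is that neighbouring regions respond to E2 together, which was not tested further.

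The hypothesis that regions gained by dex in both cell lines lie near regions raised by dex stays open. Of 2205 such regions, 38 (1.72%) had one within 100 kb, against 161 of 13201 (1.22%) regions gained by E2 alone in a cell line. The odds ratio was 1.42 (Fisher's exact p = 0.0657). A first calculation took only the 1007 regions gained by dex alone in both, of which 15 (1.49%) had one, with an odds ratio of 1.22 (Fisher's exact p = 0.458).

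The highest level of all was in a merged region of chromosome 1, 564145 to 570594. It was 21884 in untreated, 19864 in dex-treated and 12878 in E2-treated MCF-7, and 3646, 3395 and 4264 in ZR-75-1 in the same order. Chromosome 5, 134259140 to 134264342, followed, with 10762, 11067 and 6570 in MCF-7, and 1810, 1674 and 2124 in ZR-75-1. In both regions the E2 list was the lowest in MCF-7 and the highest in ZR-75-1. Whether levels so high reflect open chromatin was not examined, so they are not read as effects of a ligand.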
